A study of Arabidopsis thaliana with 24 samples.

How the data were processed

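Gene expression was measured in Arabidopsis thaliana of the Col-0 accession with 24 Affymetrix arrays of 22810 probe sets, each read by a single biotin label. The samples fall into 4 groups of 6 arrays: undifferentiated cultured cells and etiolated seedlings, each from the spaceflight and from the ground control at unit gravity. Per the labels' protocols, cells derived from hypocotyls (about 1 g on a plate) and seeds (about 75 on a plate, kept at 4 °C beforehand) were placed on nutrient agar in 60 mm dishes and kept in the dark. The flight dishes were held in BRIC canisters, passive hardware for small biological payloads, and were fixed with RNAlater in orbit after 12 days and 21 hours. Ground dishes were held in the same canister positions, per the labels' titles. The labels also give an age of 7 days for every sample, and the sources used here do not say how this age relates to the time in orbit. Total RNA was extracted with RNeasy kits, amplified with Ovation Pico WTA and labelled with the Encore Biotin Module, per the labels' protocols. Groups were taken from the sample titles and material labels, and each sample is named by its group and a replicate number that follows its hardware position. Nothing in the labels says that the dishes of a group held separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

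The deposited array values are intensity values on a linear scale, made with MAS5 in Affymetrix Expression Console, per the submitters' processing notes, and no version is given. On every array the mean of these values after trimming 2% at each end is 500, so the authors had scaled all arrays to the same total before deposit. For each material the authors also deposited a table of flight against ground with a log2 fold change, a p-value and a q-value per probe set, per the file headers. The test and the normalization behind those tables are not given in the sources used here, and they were used only for comparison.

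For the present tests the intensity was taken as log2(value + 16), which draws the differences of dim probe sets toward 0. Affymetrix control probe sets (64) were left out and the remaining 22746 were tested, with no filter on dim probe sets and no further normalization. Of these, 21158 pair with 1 gene in the platform annotation and 356 with none. The other 1232 pair with several genes or, for 413 of them, have gene identifiers that disagree. Only probe sets that pair with 1 gene were named. Coordinates are not given, since no genome build is named in the files.

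Flight was compared with ground within each material by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets at a threshold of 0.05. A fit of the 4 group means over all 24 arrays gave the difference between the flight effects of the materials, and the comparison of ground cells with ground seedlings. Single measures per array were compared by two-sided exact permutation tests. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, using for each gene the probe set with the highest mean, and again with the correlation estimated per list and with fry, which asks whether the genes of a list move one way on balance. The groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

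The 19 tested lists hold 355 gene entries on the array, and 34 further entries of the fixed lists had no probe set of their own. A list of cytosolic ribosomal proteins was left out because only 2 of its genes could be found by name. The genes named in each flight comparison are up to 8 rises and 8 falls with the largest change among those with an adjusted p under 0.05 and at least 5 of 6 flight arrays on the same side of the ground mean. Where fewer than 10 passed, the 5 with the smallest p in each direction are also given, as values. For each list the rule adds the 2 largest called members, or else the member with the smallest p. For the comparisons across materials the rule takes the 5 largest in each direction. Genes without a symbol fall outside this rule.

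The files hold no detection calls. Background was therefore set for each array as the 95th percentile of 27 bacterial control probe sets without spiked target, a choice made after the data were seen. A gene below that level on every array of a group has only a bound there. It is given as "at least N-fold", the mean of the brighter group against the mean of the dimmer group with each array raised to the background level. No fold is given where that bound falls under 1, or where the brighter group was above background on 3 arrays or fewer. In the latter case the mean of the brighter group can itself lie below background. The number of arrays limits the precision of every value. In simulated data with the real spread, 200 changed probe sets among 22746 and 10 draws, a log2 change of 2 was called for 1.94% of changed probe sets in the cells and 50.6% in the seedlings, and a change of 4 for 62.3% and 93.8%. The share of calls that were false was 2.75% and 5.08%. The simulated noise was normal and independent between probe sets and arrays. These shares therefore do not cover correlated genes, outlying arrays or shifts of whole arrays.

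Alternatives covered the normalization between arrays, the pseudocount, filters on dim probe sets, hardware positions and canisters as blocks, array weights, other variance priors, thresholds and each array left out in turn. Filters and a covariate built on the control probe sets, and a repeat of the list test without 1 seedling array, were added after the data were seen.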

Results

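The 24 arrays describe undifferentiated cultured cells and dark-grown seedlings after flight or on the ground, with 6 arrays in each of the 4 groups. The comparison of flight with ground asks which transcripts differ in the spaceflight environment, and the pair of materials asks whether cells without organs differ in the same genes as whole seedlings. Signal over background differed widely between the materials. In the cells, 26.3% ± 25.6 (SD, n = 6) of probe sets were above background on flight arrays and 18.7% ± 4.72 on ground arrays. Flight replicate 5 alone reached 76.7%, and without it the flight mean was 16.3% and the difference from ground -2.40 points (exact permutation p = 0.541), a comparison chosen after the data were seen. In the seedlings the shares were 62.0% ± 3.54 and 49.9% ± 8.68 (SD, n = 6). The seedling difference of 12.1 percentage points passed an exact permutation test (p = 0.0173, adjusted p = 0.032 over 24 comparisons of array measures), while that of the cells, 7.68 points, did not (exact p = 0.734, adjusted p = 0.80). The spiked cre hybridization control differed by -0.86 on the log2 scale between flight and ground arrays of seedlings (17.02 ± 0.51 against 17.88 ± 0.22, SD, n = 6, exact p = 0.00649, adjusted p = 0.0173). The median correlation between arrays of the same group was 0.310 in the cells and 0.845 in the seedlings. None of the 276 pairs of arrays was identical, and the highest correlation was 0.931.

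**Figure D1:**
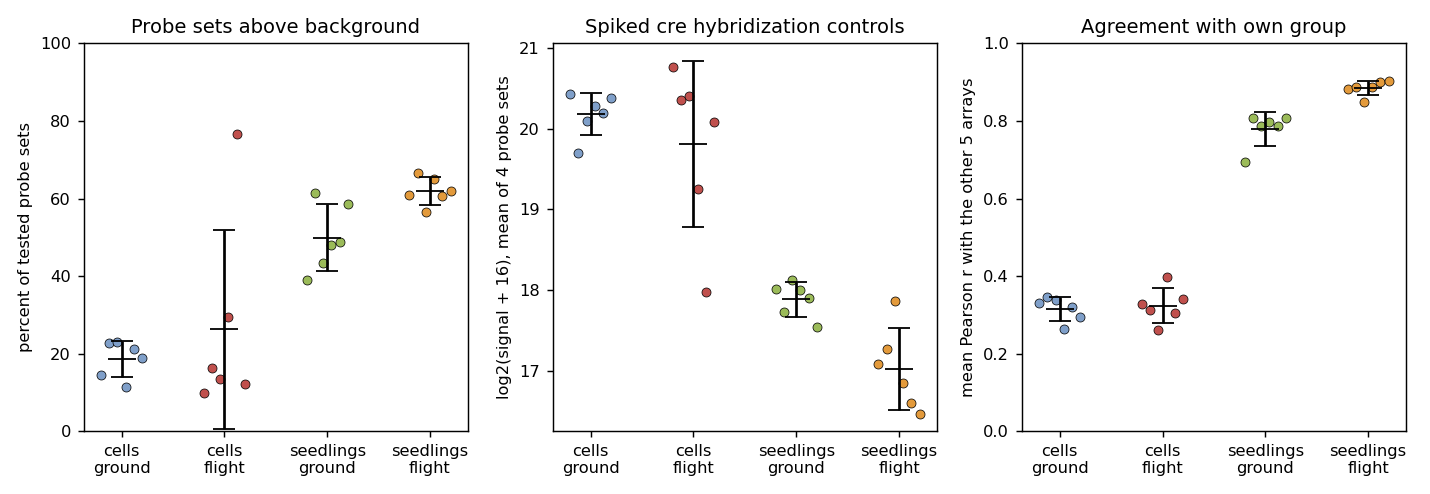
Percent of probe sets above background, log2 level of the cre hybridization controls and mean correlation with the other arrays of the group for each of the 24 arrays (points), with the mean and SD of each group (bars, n = 6). One flight array of cells reached 76.7% above background, and the cell arrays correlated less with each other than the seedling arrays did.

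In cultured cells, 7 of 32 heat shock genes rose in flight, and the list passed by camera (adjusted p = 1.7e-30) but not with an estimated correlation (adjusted p = 0.0785). HSFA2, a transcription factor that drives the heat shock response, rose by 4.83 log2 units (15.28 ± 2.12 in flight against 10.45 ± 0.68 on the ground, SD, n = 6, SE 0.82, adjusted p = 0.000102, higher in 6 of 6 flight arrays). The chaperones HSP70 (4.28, adjusted p = 0.00234), HSP70B (3.99, adjusted p = 0.00662) and HSP90.1 (3.97, adjusted p = 0.00662) rose, as did HSP101 (4.21, adjusted p = 0.00243), which dissolves protein aggregates. HOP3, a co-chaperone that links HSP70 and HSP90, rose by 3.69 (adjusted p = 0.0236), and the small heat shock protein gene HSP17.4 by 3.67 (adjusted p = 0.0241). HUP26, a hypoxia-responsive gene, rose by 3.92 (adjusted p = 0.00738). These were the 8 probe sets called by limma among those tested, all higher in flight by more than 2-fold, and 1310 had an unadjusted p under 0.05, where chance gives 1137.3. HSP101, HSP90.1 and HUP26 were above the ground mean in 5 of 6 flight arrays and the others in 6 of 6. HOP3 was above background on 3 of 6 ground arrays, and HSFA2, HSP101, HSP70B and HUP26 on 5 of 6. The 3' minus 5' log2 signal, a sign of RNA integrity, differed between flight and ground by 0.39 for the GAPDH control (exact p = 0.16, adjusted p = 0.256) and by -0.03 for ubiquitin (exact p = 0.911, adjusted p = 0.911). For actin it differed by 1.28 (exact p = 0.0108, adjusted p = 0.026), with the 3' probe set above background on 4 flight and 3 ground arrays and the 5' probe set on 1 flight and 3 ground arrays, and with ground replicate 4 at -2.71. The fit drew the variances of all probe sets to 1 value, and without variance moderation no probe set passed (limma without eBayes, smallest adjusted p = 0.138, 1355 at an unadjusted p under 0.05). The count fell to 1 with a pseudocount of 1, over probe sets above background (a filter chosen after the data were seen) or without flight replicate 1 or 4, to 4 without flight replicate 6 and to 5 without flight replicate 2 or ground replicate 2. It rose to 22 with a trended robust prior (20 higher, 2 lower, 6 shared with the 8) and to 39 with all 24 arrays in 1 fit (23 higher, 16 lower, 7 shared). HSFA2 passed in each of the 12 fits with 1 array left out, at 4.40 to 5.36. No other gene passed without flight replicate 1 or 4, nor did HSP101 without ground replicate 1 or HSP90.1 without flight replicate 6. HUP26, HOP3 and HSP17.4 also lost their calls without flight replicate 2 or 6 or ground replicate 2, HOP3 without ground replicate 4, and HSP17.4 without ground replicate 1 or 3.

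As a list, the 32 heat shock and chaperone genes were higher in flight cells, with a median log2 difference of 2.13 and 27 of 32 members higher. Over all genes 7 members rose and 25 did not pass, and adjusted over the list alone 18 rose. The test by camera gave an adjusted p of 1.7e-30, against adjusted p = 0.0785 with an estimated correlation and adjusted p = 0.117 by fry. The list's mean level was 11.89 ± 1.39 in flight and 9.87 ± 0.32 on the ground (SD, n = 6, exact permutation p = 0.0108, adjusted p = 0.206 over 19 lists). Single flight arrays ranged from 9.83 to 13.2 and ground arrays from 9.49 to 10.3. Among members chosen after their values were seen, the heat shock factors HSFA7A (13.31 against 10.02) and HSFB2B (a log2 difference of 3.27) and the cochaperone gene BAG6 (2.95) rose adjusted over the list alone and did not pass over all genes, with 3, 1 and 1 ground arrays above background. The constitutive chaperone gene HSC70-1 differed by -0.84. Root markers (median -0.14) and shoot epidermis markers (median -0.04) showed no called difference beside it. Only 2 of 16 and 0 of 8 of these markers were above background on at least 6 of 12 arrays, so they are a weak comparison.

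The largest falls in cells did not pass. SKB1, a protein arginine methyltransferase, averaged 5.58 in flight, where no array was well above background, and 8.84 on the ground (adjusted p = 0.133). AGP20, an arabinogalactan protein, averaged 6.54 in flight and 9.79 on the ground (adjusted p = 0.133). The dynamin-related DRP4C averaged 6.29 and 9.42 (adjusted p = 0.203). SKB1 was above background on 1 ground array, AGP20 and DRP4C on 3 each, and none of them on any flight array. The A-type cyclin CYCA3;4 differed by -2.81 (adjusted p = 0.434, above background on 1 flight and 3 ground arrays). The chloride channel family gene CLC-A differed by -2.72 (adjusted p = 0.547, above background on 1 array of each group).

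None of the other 18 lists passed in cells. Many of their genes were too dim there to be measured. On at least 6 of 12 arrays, 0 of 24 photosynthesis, 0 of 8 shoot epidermis and 0 of 13 salicylate genes were above background. So were 1 of 22 root hair, 1 of 9 gravitropism, 2 of 25 auxin and 3 of 29 cell cycle genes, against 14 of 21 hypoxia and 17 of 23 carbon starvation genes. For the dim lists a median near 0 does not show that the genes were unchanged. The hypoxia list (21 genes) had a median of 0.27 (adjusted p = 0.32) and 1 called member, HUP26. Without flight replicate 5, the array with 76.7% of probe sets above background, the hypoxia list (0.44) and the carbon starvation list (0.46) passed as well, both at an adjusted p of 0.0111. Over probe sets above background, a filter chosen after the data were seen, ER stress (-1.06) and cell wall genes (-0.99) passed, both at an adjusted p of 0.0138 by camera. ER stress genes had a median of -0.34 (adjusted p = 0.32), and ERDJ3B, a co-chaperone of the endoplasmic reticulum, differed by -1.57 (adjusted p = 0.868). Touch and calcium genes had a median of -0.43 (adjusted p = 0.325), with WRKY33, a defence regulator, at -1.76. The reactive oxygen list had a median of -0.38 (adjusted p = 0.543), with the NADPH oxidase gene RBOHF at -2.12. Cell wall genes had a median of -0.33 (adjusted p = 0.32), and 1 member fell adjusted over the list alone, the expansin EXPA3, at 6.00 in flight and 8.63 on the ground and above background on no array. Among stress and hormone lists, medians were -0.36 for ethylene (adjusted p = 0.32), with the F-box gene EBF2 at -1.49, and -0.34 for salicylate (adjusted p = 0.32), with the glucanase gene PR2 at -1.69. They were 0.25 for jasmonate (adjusted p = 0.506), with the defensin PDF1.2A at 8.05 and 6.75, and 0.13 for abscisic acid, drought and cold (adjusted p = 0.79), with RD20 at 6.14 in flight and 7.85 on the ground.

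Auxin genes in cells had a median of 0.12 (adjusted p = 0.506), with the repressor IAA14 at 8.54 in flight and 7.13 on the ground. The gravitropism list had a median of 0.46 (adjusted p = 0.459), with the phospholipase gene SGR2 at 8.14 and 6.58. Root hair genes had a median of -0.16 and a mean of 0.02, in the direction of the test (adjusted p = 0.978), with the extensin-like LRX1 at 2.16. The root marker list had an adjusted p of 0.79, with the homeobox gene GL2 at 9.23 and 7.10, and the shoot epidermis list also 0.79, with the wax gene CER3 at -1.13. Carbon starvation genes had a median of 0.10 (adjusted p = 0.344), with the trehalose phosphate synthase family gene TPS8 at 14.20 in flight and 12.10 on the ground. The medians of photosynthesis (-0.16, with the chlorophyll regulator GUN4 at -1.53) and cell cycle (0.19, with the cyclin CYCD3;3 at -1.74) both had an adjusted p of 0.506. The seed storage list had a median of -0.35 (adjusted p = 0.79), with the oleosin OLEO1 at 8.42 and 6.78. No gene given for these lists passed over all genes except HUP26. TPS8 was above background on all arrays, and those given with a log2 difference on 1 to 5 arrays of each group, except ERDJ3B and HUP26, each on all arrays of 1 group. The others given by their means were not well above background in at least 1 group.

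In etiolated seedlings 4 probe sets passed between flight and ground, 1 higher and 3 lower, and none of their genes has a symbol, so they were named after their values were seen. AT4G34950 averaged 7.42 ± 0.55 in flight and 5.13 ± 0.33 on the ground (SD, n = 6, adjusted p = 0.0274), above background on 5 flight arrays and on no ground array. AT5G39090 averaged 5.10 ± 0.42 in flight and 7.54 ± 0.62 on the ground (SD, n = 6, adjusted p = 0.0274), above background on 3 ground arrays and on no flight array. AT3G59120 averaged 4.66 in flight and 6.99 on the ground (adjusted p = 0.027) and AT4G21650 averaged 4.65 and 6.97 (adjusted p = 0.0274), both not well above background on any array. A further 1823 probe sets, these included, had an unadjusted p under 0.05 (760 higher, 1063 lower). The count was 0 without flight replicate 1, 4 or 6 or ground replicate 4 (limma, 1426 to 1896 at an unadjusted p under 0.05). It was also 0 over the brighter probe sets (smallest adjusted p = 0.203), in the larger canister (0.105), with a trended prior (0.0532) and with all 24 arrays (0.643). The same held with the hardware position as a block (0.383) and at an adjusted p of 0.01. In alternatives chosen after the data were seen, it was 0 above background (0.218) and with the cre covariate (0.358). It was 1 without flight replicate 3 or 5, 2 without ground replicate 2 or 6, and 8, 10 and 9 without ground replicates 1, 3 and 5.

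Named seedling genes with the smallest p did not pass. The lipid transfer protein gene LTP6 was at least 1.76-fold higher in flight (8.44 against 5.51, adjusted p = 0.179). WRKY71 averaged 6.94 and 4.86 (adjusted p = 0.179), the peroxisomal thiolase family gene PKT4 7.54 and 5.76 (adjusted p = 0.191) and NUDT12 7.05 and 5.22 (adjusted p = 0.241), with ground levels not well above background. UGP3, a plastid UDP-glucose pyrophosphorylase, differed by 1.63 (SE 0.35, adjusted p = 0.246, above background on 5 flight arrays and 1 ground array). On the lower side, the photosystem II gene PSBP-2 averaged 5.32 in flight and 7.57 on the ground (adjusted p = 0.108), and MYB102 5.26 and 7.01 (adjusted p = 0.317). They were above background on 2 and 1 ground arrays, and on no flight array. DXPS1 averaged 4.84 in flight and 6.59 on the ground (adjusted p = 0.292), the myosin XIJ 4.46 and 6.39 (adjusted p = 0.292) and the gibberellin oxidase GA2OX8 4.56 and 6.33 (adjusted p = 0.317, above background on no array).

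Across the gene lists, photosynthesis, cell wall and shoot epidermis genes were higher in flight seedlings by camera, and heat shock, carbon starvation and root hair genes lower, and none of the 6 passed with an estimated correlation. Of 24 photosynthesis and chlorophyll genes 19 were higher (median 0.48, adjusted p = 3.8e-05; adjusted p = 0.323 with an estimated correlation). None passed over all genes and 4 rose adjusted over the list alone. CHLH, a subunit of the magnesium chelatase of chlorophyll synthesis, differed by 2.32 (SE 0.51, adjusted p = 0.292 over all genes and 0.0106 over the list alone). The others, chosen after their values were seen, were plastocyanin PETE1 (1.53), PSBO1 of the oxygen-evolving complex (1.08) and the antenna gene LHCB5 (1.00). On ground arrays CHLH was above background on 2, PETE1 on 1, PSBO1 on 3 and LHCB5 on 4 of 6. The mean of this list gave an exact permutation p of 0.0152 (adjusted p = 0.288 over 19 lists).

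Of 27 cell wall genes 22 were higher (median 0.53, adjusted p = 0.00234; adjusted p = 0.559 with an estimated correlation), with the expansin EXPA6 at least 1.55-fold higher (8.26 against 6.19, adjusted p = 0.38). Of 8 shoot epidermis genes 7 were higher (median 0.53, adjusted p = 0.0421; adjusted p = 0.559 with an estimated correlation). PDF1, an epidermal marker, differed by 2.09 (SE 0.52, adjusted p = 0.317 over all genes) and was the 1 member that rose adjusted over the list alone (adjusted p = 0.00999). Of 23 carbon starvation genes 21 were lower (median -0.44, adjusted p = 0.00234; adjusted p = 0.559 with an estimated correlation), with SEN1, induced in darkness, at -1.06 and the glutamate dehydrogenase GDH2 at -0.82, both named after their values were seen. SAG13, its member with the smallest p, was above background on no array. Of 22 root hair genes 17 were lower (median -0.52, adjusted p = 0.0108; adjusted p = 0.323 with an estimated correlation; exact permutation p of the list mean = 0.0303, adjusted p = 0.288), with COBL9, needed for root hair growth, at -1.46 (adjusted p = 0.406, above background on 1 flight and 2 ground arrays). Of 32 heat shock genes 30 were lower (median -0.76, adjusted p = 0.00284; adjusted p = 0.611 with an estimated correlation), with the small heat shock protein gene HSP18.2 at -2.14 (adjusted p = 0.485, above background on 4 flight and 5 ground arrays). By fry the adjusted p of these 6 lists lay between 0.195 and 0.579. The exact permutation p of the list mean was 0.868 for heat shock (adjusted p = 0.97) and 0.21 for shoot epidermis genes (adjusted p = 0.443). It was 0.104 for carbon starvation and 0.0823 for cell wall genes (adjusted p = 0.323 for both).

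Each of these list differences stands beside the brighter flight arrays (12.1 percentage points more probe sets above background, cre control at -0.86) and a 25S ribosomal RNA control that differed by -0.94 in flight (exact p = 0.013, adjusted p = 0.0283 over the array measures and 0.192 over 38 tests of plant control probe sets). With the cre level of each array as a covariate, an alternative chosen after seeing the data, no list passed by camera (smallest adjusted p = 0.0561, 5 lists at an unadjusted p under 0.05). The medians with that covariate were -0.15 for heat shock, 0.32 for photosynthesis, 0.41 for cell wall, -0.29 for carbon starvation, -0.40 for root hair and 0.37 for epidermis genes. Ground replicate 1 stood apart from the other seedling arrays, with a heat shock list mean of 13.9 against 8.34 to 8.63 on the other ground arrays and 8.47 to 8.85 on flight arrays. Without it the heat shock median was 0.039 (adjusted p = 0.34), the epidermis median 0.25 and the carbon starvation median -0.17 (adjusted p = 0.34 for both), while photosynthesis (0.47, adjusted p = 5.2e-05), root hair (-0.66, adjusted p = 0.00446) and cell wall genes (0.22, adjusted p = 0.0317) passed. Root markers (-0.40) and hypoxia genes (0.45) then passed too, both at an adjusted p of 0.0139, and no list passed with an estimated correlation (smallest adjusted p = 0.152, 3 lists at an unadjusted p under 0.05). Photosynthesis reached 0.80 without flight replicate 3. The epidermis call was also lost without flight replicate 2, 4 or 6 or ground replicate 6, and with the hardware position as a block.

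**Figure D2:**
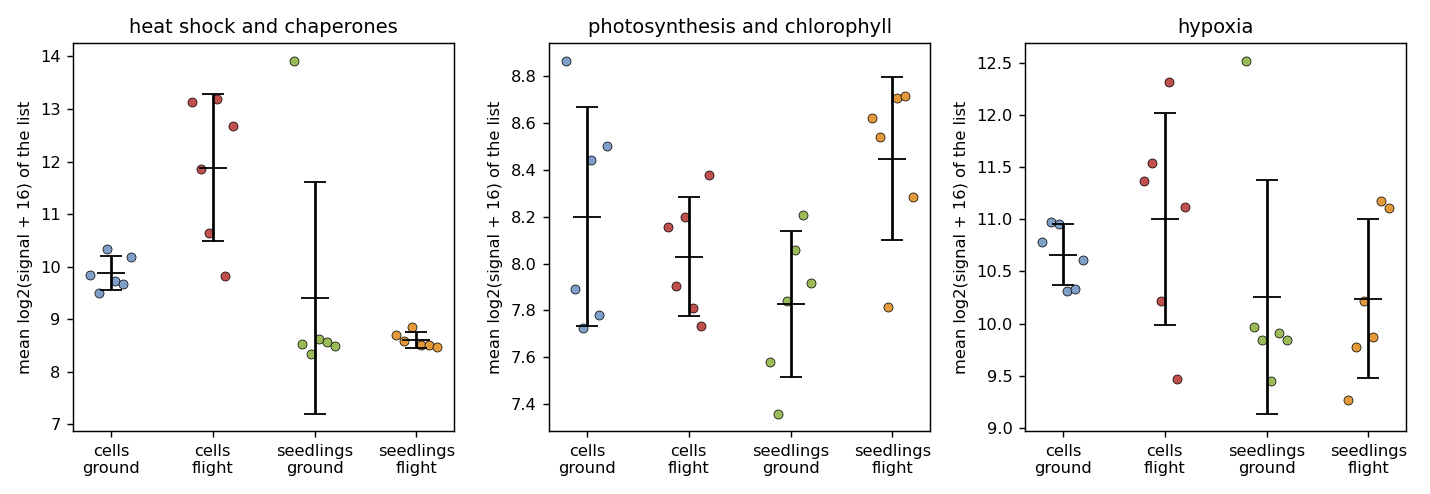
Mean log2 level of the heat shock, photosynthesis and hypoxia lists on each array (points), with group means and SD (bars, n = 6). Flight cells spread from 9.83 to 13.2 for the heat shock list, and ground seedling replicate 1 stands at 13.9.

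The remaining 13 lists did not pass in seedlings with all arrays and the chosen settings. Root markers had a median of -0.10 (adjusted p = 0.814), with the auxin efflux carrier PIN2 at -1.01. The auxin list had a median of -0.05 (adjusted p = 0.802), and the gravitropism list one of 0.12 (adjusted p = 0.382), each with the carrier PIN3 at 9.35 in flight and 8.15 on the ground. Cell cycle genes had a median of 0.29 (adjusted p = 0.0532), with the cyclin CYCA3;1 at 6.43 in flight and 5.19 on the ground, where it was not well above background. This list passed without flight replicate 3 or 5 or ground replicate 4 or 5 (adjusted p of 0.00593 to 0.043) and with quantile normalization (0.34, adjusted p = 0.0339). ER stress genes had a median of 0.26 (adjusted p = 0.382), with the co-chaperone ERDJ3A at -2.27, against the direction of its list. The touch list had a median of -0.03 and a mean of 0.04 (adjusted p = 0.802), with the calmodulin-like CML42 at -1.11, and the hypoxia list a median of -0.06 and a mean of -0.02 (adjusted p = 0.872), with the transcription factor HRA1 at 0.89. In both of these the test read higher, and in the seed storage list it read lower (median 0.01, mean -0.14, adjusted p = 0.802), with AT3G15670 at -0.87. Without flight replicate 1 the seed storage list passed (median -0.54, adjusted p = 0.027). Reactive oxygen genes had a median of -0.27 (adjusted p = 0.371), with the glutathione transferase GSTU24 at -1.32. Medians were -0.11 for ethylene (adjusted p = 0.802), with the ethylene synthesis gene ACS2 at -1.39, and -0.41 for jasmonate (adjusted p = 0.135), with the repressor JAZ7 at -1.42. Salicylate genes had a median of -0.15 (adjusted p = 0.382). CYP71A13 of camalexin synthesis averaged 5.28 in flight and 6.97 on the ground (adjusted p = 0.334). It was the 1 member that fell adjusted over the list alone, above background on 1 ground array and no flight array. Abscisic acid, drought and cold genes had a median of -0.23 (adjusted p = 0.382), and RD22 (10.67 in flight against 9.16 on the ground, adjusted p = 0.317 over all genes) rose adjusted over the list alone. No gene given for these lists passed over all genes. ERDJ3A, PIN2 and ACS2 were above background on 1 flight array each and on 1 or 2 ground arrays, JAZ7 on 3 and 4, AT3G15670 on 4 and 3, PIN3 on 6 and 4, RD22 on 6 and 5 and CML42 on 5 and 6.

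**Figure D3:**
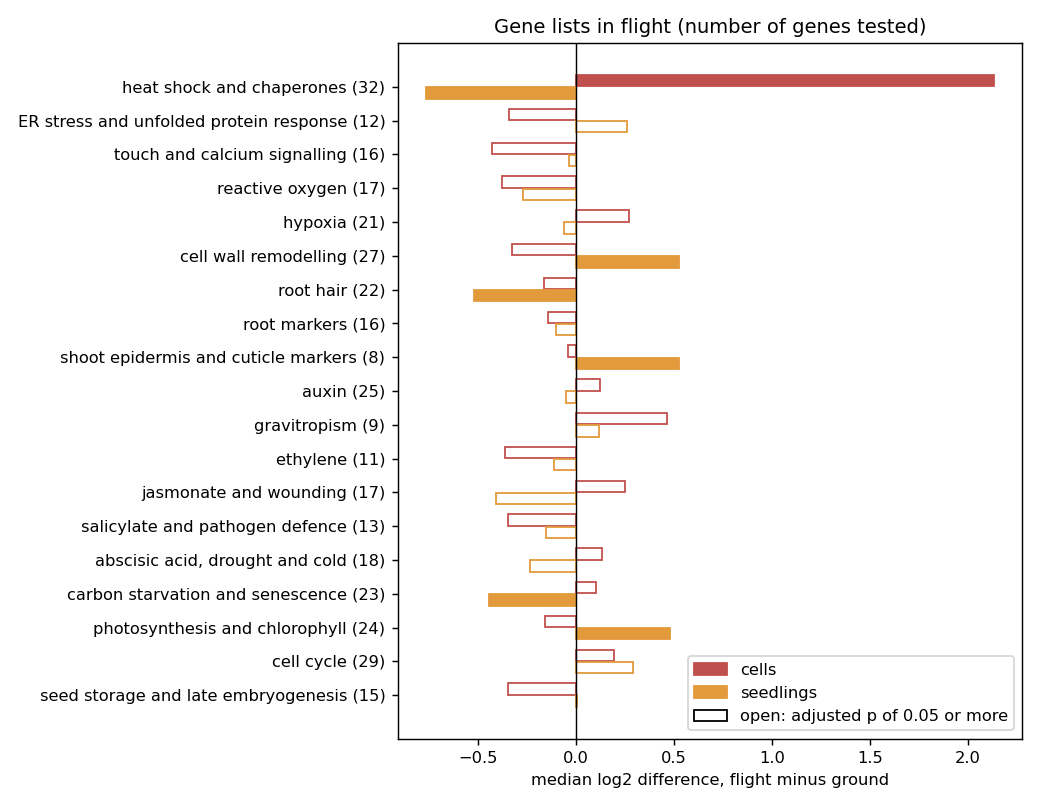
Median log2 difference of flight minus ground for each of the 19 gene lists (bars), in cells and in seedlings, with filled bars for an adjusted p under 0.05 by camera and the number of genes tested in parentheses. The heat shock list has a median of 2.13 in cells and -0.76 in seedlings, and the latter is 0.039 without ground replicate 1.

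The difference between the flight effects of cells and seedlings asks whether the materials respond unequally. No probe set passed in limma, and 1508 had an unadjusted p under 0.05, where chance gives 1137.3. HSFA2 had the smallest adjusted p (0.0644), with a flight effect 6.41 larger in cells (SE 1.22), and the effects of HSP101 (5.23), HSP70 (4.61) and HSP90.1 (4.58) were also larger in cells without passing. The values of HSFA2 and HSP101 hold seedling ground replicate 1, at 15.77 and 15.73 against means of 8.55 and 9.39 on the other 5 ground arrays. Flight seedlings averaged 8.17 and 9.43 for these 2 genes. The differences of HSP70 and HSP90.1 hold that ground array as well, on which 30 of 32 heat shock genes were higher. For both, ground seedlings spread more than flight seedlings (SD 1.82 against 0.24 for HSP70, n = 6). How much that array adds to their differences was not tested. The metallothionein MT3 had an effect of -3.60 in cells relative to seedlings (adjusted p = 0.301, above background on 1 flight and 4 ground arrays of cells). SKB1 and the arabinogalactan gene AGP20 (adjusted p = 0.301 for both), the expansin EXPA3 (adjusted p = 0.371) and the glucan synthase family gene CSLC6 (adjusted p = 0.388) were not well above background in flight cells, nor was the MADS-box gene TT16 (adjusted p = 0.366) in ground cells and seedlings, so no size is given for them. The count was 5 without cells flight replicate 5 and 1 without cells flight replicate 3, seedlings flight replicate 2 or seedlings ground replicate 2, 3, 5 or 6. By camera, 4 lists differed: heat shock (median difference 2.82, adjusted p = 4.2e-23; adjusted p = 0.111 with an estimated correlation), cell wall (-1.05, adjusted p = 0.00102; 0.111 estimated), photosynthesis (-0.55, adjusted p = 0.00404; 0.111 estimated) and carbon starvation (0.52, adjusted p = 0.00936; 0.519 estimated). Permutation of list means within materials (20000 draws) gave p = 0.0103 for heat shock (adjusted p = 0.0983), p = 0.00625 for cell wall (adjusted p = 0.0983), p = 0.0175 for photosynthesis (adjusted p = 0.105) and p = 0.199 for carbon starvation (adjusted p = 0.46). The heat shock, cell wall and carbon starvation values hold the outlying list means of seedling ground replicate 1. Without that array, an alternative chosen after the data were seen, the median difference was 1.92 for heat shock (adjusted p = 6.8e-15 by camera), -0.65 for cell wall (adjusted p = 0.0113) and -0.54 for photosynthesis (adjusted p = 0.00532), while carbon starvation did not pass (0.42, adjusted p = 0.336). With an estimated correlation the adjusted p was 0.0837 for the first 3 lists, and by permutation of list means 0.148.

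No probe set was called in both materials, where 0.00035 shared rises were expected by chance (Fisher's exact p = 1). At an unadjusted p under 0.05, 31 probe sets were higher in both against 23.02 expected (Fisher's exact p = 0.105, adjusted p = 0.419) and 29 were lower in both against 29.0 expected (Fisher's exact p = 1). Across probe sets, which are not independent replicates, the log2 differences of the materials correlated at r = -0.00653 (Spearman's rho -0.00643).

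On the ground, cells and seedlings differed in 8675 probe sets, 6282 higher and 2393 lower in cells, each by more than 2-fold. Over probe sets above background in both materials, a filter chosen after the data were seen, 386 were higher and 700 lower. Background signal was 952 ± 176 in ground cells and 188 ± 54.4 in ground seedlings (SD, n = 6, exact permutation p = 0.00216, adjusted p = 0.00649). The cre level was 2.30 higher in ground cells, with the same p-values. How far this background adds to the higher calls was not tested. Higher in cells were the defensin-like LCR67 (at least 23.64-fold, 12.18 ± 0.70 against 4.92 ± 0.22, SD, n = 6, adjusted p = 4.4e-12), ARD3 of the methionine cycle (5.44, SE 0.96, adjusted p = 4.1e-05), the glyoxylate cycle enzyme gene ICL (5.34, SE 0.84, adjusted p = 6.9e-06), the thioredoxin TH8 (5.30, SE 0.64, adjusted p = 4.7e-08) and the phosphatase gene PS2 (at least 9.50-fold, adjusted p = 4.0e-08). ARD3 and TH8 were above background on 3 of 6 seedling ground arrays. ARD3 and ICL were high on seedling ground replicate 1 (14.27 and 15.05) against means of 7.15 and 8.80 on the other 5 ground arrays, and without it their differences were 6.63 and 6.38. Lower in cells were the lectin family gene JAL22 (at least 21.8-fold, adjusted p = 1.6e-13), MLP28 (at least 16.3-fold, adjusted p = 1.8e-11), the glycine-rich protein gene GRP-3 (at least 24.6-fold, adjusted p = 9.7e-10), EBP (-6.81, SE 0.56, adjusted p = 9.5e-13) and the actin ACT2 (-6.01, SE 0.62, adjusted p = 1.1e-09). EBP was above background on 4 and ACT2 on 3 of 6 cell arrays. The median of all probe sets was 0.77 higher in cells, and quantile normalization turned the balance to 1876 higher and 2611 lower (median 0.14), with the 10 named calls kept under each of the 27 or 28 alternatives run for them. Among lists, ethylene (median -0.26) and carbon starvation genes (-0.80) were lower in cells relative to the other genes, both at an adjusted p of 0.0425, with adjusted p = 0.136 and 0.666 with an estimated correlation.

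By the authors' deposited tables, 0 probe sets had a q-value under 0.05 in cells (smallest 0.155, 1292 at a p-value under 0.05) and 2 in seedlings (smallest 0.035, 2005 at a p-value under 0.05). For HSFA2 in cells the authors' deposited table gives a log2 fold change of 5.14 with a p-value of 2.17e-05 and a q-value of 0.155. The authors' deposited table gives 28 of the 32 heat shock genes as higher in flight cells, 17 of them with a p-value under 0.05. Across probe sets the log2 fold changes of the deposited tables correlated with the present differences at 0.971 in cells and 0.973 in seedlings.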

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

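The tests of the heat shock and photosynthesis lists without ground seedling replicate 1, both tests of that array, and the use of the cre control level as a covariate were chosen only after the result was seen. Of 74 groups of 6 arrays examined for an array far from the rest, 10 had one, where chance gives about 1 in 20, or 3.7.

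Among the cells, flight replicate 5 had 76.7% of probe sets above background, far from the 9.94% to 29.4% of the other flight arrays. The actin 3' minus 5' difference of ground replicate 4 was -2.71, far from -0.32 to 0.53 on the others, in probe sets that were each above background on 3 of 6 ground arrays. HSP101 stood at 7.53 on ground replicate 1 against 10.92 to 11.61 on the other ground arrays, and HUP26 at 7.97 on ground replicate 2 against 12.08 to 12.77. In flight seedlings, AT3G59120 stood at 5.49 on replicate 5 against 4.26 to 4.67 on the others. Ground seedling replicate 1 lay far from the other ground arrays in 5 of the measures examined, which took in only the lists called in flight. Its mean correlation with its group was 0.693 (others 0.786 to 0.808), and its list means were 13.91 for heat shock (8.34 to 8.63), 7.72 for cell wall (8.95 to 9.40), 6.53 for shoot epidermis (8.47 to 9.13) and 12.77 for carbon starvation (10.56 to 10.86). Of the 13 other lists, examined after the data were seen, 5 also had that array far from the rest: hypoxia (12.52, others 9.45 to 9.97), root markers (6.35, 8.29 to 8.60), reactive oxygen (11.29, 9.84 to 10.27), jasmonate (8.26, 7.18 to 7.40) and ethylene (9.04, 9.62 to 9.88). Between the materials, the flight effects differed by camera in 4 lists, with median differences of cells minus seedlings of 2.82 for heat shock, -1.05 for cell wall, 0.52 for carbon starvation and -0.55 for photosynthesis. With an estimated correlation none of the lists passed (smallest adjusted p = 0.111, 4 at an unadjusted p under 0.05). Of 100 regroupings of the arrays within materials, 6 gave as many called lists (real 4, highest other 6), so chance cannot be excluded for that count. For the 0 probe sets called (limma, 1508 at an unadjusted p under 0.05) the regroupings decide nothing, since all 100 give at least 0 by construction (highest other 1).

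The first pattern is the higher heat shock list in flight cells. For brightness that moves with flight, the list's median was 2.42 with each array's cre control level as a covariate against 2.13 without it. That level differed by -0.37 between flight and ground cells (exact permutation p = 0.487, adjusted p = 0.589). It was 17.98 on flight replicate 5 against 19.26 to 20.77 on the other flight arrays. The covariate thus largely follows that array and argues only weakly against brightness. A single array is argued against, since the lowest median without 1 array was 1.74. Of 100 splits of the 12 arrays only the real one gave as many called probe sets (8, highest other 7). This argues against chance for the number of probe sets only by a narrow margin, and does not exclude chance. The splits with 7 calls swapped only 1 flight array for 1 ground array, so they lie close to the real grouping. Other splits with 1 such swap gave 0 or 1. As many called lists came from 61 splits (real 1, highest other 4), so chance is not excluded for the number of lists either. A response to flight may underlie the rise, but handling and fixation moved with flight and stay open, and no probe set passed without variance moderation (limma, 1355 at an unadjusted p under 0.05).

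The second pattern is the set of 6 lists shifted in flight seedlings. Ground replicate 1 is a candidate source of the lower heat shock list, whose median went from -0.76 to 0.039 without it, and is argued against for photosynthesis, which stood at 0.47 without it. Of all 6 lists, 3 kept direction and call without that array. By the rule set beforehand, at least 50% kept argues against that array as the source of the set, and the count just meets it. Slopes on the cre level within groups gave at least 50% of the shift in 2 of 6 lists, which by its rule, taken alone, argues against brightness. That count ran from 0 to 4 when 1 array was left out, so the test cannot decide. With the cre level as a covariate, 0 of the 6 lists kept their call. With outcomes so near their bounds, neither this array nor brightness was firmly told apart from flight for the set. On that array a cell sample is argued against, since its mean correlation was 0.347 higher with the other seedling arrays than with the cell arrays, and so is noise of a dim array, since 0% of 10000 random lists had a median excess as large as the 5.52 of heat shock. Of 100 splits, 2 gave as many called probe sets (real 4, highest other 5), a share under the 5% set beforehand although 1 other split gave more calls, and 17 as many called lists (real 6, highest other 9), which does not exclude chance, and a biological difference of that dish or of flight stays untested.

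The third pattern is the low agreement between arrays of cells, with a median correlation of 0.310 that was 0.816 over the 454 brightest probe sets. The median correlation was 0.124 over the next 1820 probe sets, and -0.068, -0.076 and -0.014 over the 3412, 5687 and 11373 dimmer ones. Little labelled target against the hybridization controls might account for the low agreement. Over the 12 arrays the cre level correlated with agreement at r = -0.137 (permutation p = 0.664, adjusted p = 0.664; Spearman's rho -0.497, permutation p = 0.105, adjusted p = 0.21). Without the 2 arrays farthest from the median cre level r was -0.374, with -0.0531 in flight arrays and -0.569 in ground arrays, and the value over 12 arrays lies between the bounds set beforehand, so the explanation stays open. The design gives no group that would test a biological explanation. In the comparison of ground cells with ground seedlings 1 of 100 splits, the real one, gave as many calls (8675, highest other 3062). This argues against chance for the count, but it cannot separate biology from the difference in array background between the materials.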

How the results depend on the processing

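The filter on background, the cre covariate and the list test without 1 array were chosen only after the result was seen. The calls of 8 probe sets and 1 list in cells, 4 probe sets and 6 lists in seedlings, 0 differences between materials and 8675 between ground groups were recomputed, and the cause of a change was not tested except where fewer arrays, fewer probe sets or a stricter threshold were used. In cells the count was 5 with quantile normalization, 1 with a pseudocount of 1, 5 over the brighter probe sets (above the median), 22 with a trended robust prior (20 higher, 2 lower), 0 without variance moderation (1355 at an unadjusted p under 0.05), 39 with all 24 arrays in 1 fit (23 higher, 16 lower), 1 over the 2557 probe sets above background, and 1 to 11 without 1 array. Called lists in cells were 0 with an estimated correlation (2 at an unadjusted p under 0.05) and by fry (4), 3 above background, where ER stress (-1.06) and cell wall (-0.99) passed too (adjusted p = 0.0138 for both), and 1 to 3 without 1 array. In seedlings limma called 0 over the brighter probe sets (924 at an unadjusted p under 0.05), in the larger canister (1519), with a trended prior (1823), with all 24 arrays (612), at an adjusted p of 0.01 (1823), above background (1054) and with the cre covariate (1179), 10 with array weights, and 0 to 10 without 1 array. Called lists in seedlings were 0 with an estimated correlation (2 at an unadjusted p under 0.05), by fry (2), with the cre covariate (5) and with an estimated correlation without ground replicate 1 (3), and 5 to 7 without 1 array, and jasmonate passed above background (-0.41, adjusted p = 0.0154). Without 1 array the heat shock median in seedlings ran from -0.94 to 0.039, turning sign without ground replicate 1 by both correlations. In the seedlings hypoxia ran from -0.29 to 0.45, called without ground replicate 1, and seed storage and late embryogenesis, seedlings, from -0.54, called without flight replicate 1 (adjusted p = 0.027), to 0.29. Probe sets that differed between materials were 3 above background and 0 to 5 without 1 array. Between ground groups there were 4487 with quantile normalization, 3502 over the brighter probe sets (1093 higher, 2409 lower) and 1086 above background (386 higher, 700 lower). Calls shared at an unadjusted p under 0.05 were 31 higher and 29 lower.

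With the hardware position as a block the seedling count was 0 (1821 at an unadjusted p under 0.05), the epidermis list lost its call (adjusted p = 0.107) and the cell cycle list gained one (0.29, adjusted p = 0.0387), and the block changed no other count or list call, at 8 probe sets and 1 list in cells, 6 lists in seedlings and 0 between materials (1542 at an unadjusted p under 0.05). The position does not pair samples, since deviations of flight and ground arrays at the same position correlated at -0.053 to 0.104 in cells and -0.020 to 0.057 in seedlings, with 1 and 0 of 6 pairs over 0.1, and 3 and 2 of 6 correlated best with their own position. Over 38 list results 626 of 724 alternatives kept direction and call, and over 82 gene results 2019 of 2159. Most of these results were not called at the start, so these counts say little about the calls. The genes called in flight kept their call in 13 (HSP17.4) to 26 (HSFA2) of 27 alternatives in cells and in 10 to 14 of 25 in seedlings. The heat shock list in cells kept its call in 17 of 19, and the epidermis list in seedlings in 9 of 20. With the highest negative control as background, 19.1%, 12.1%, 57.6% and 42.6% of probe sets were above it in flight cells, ground cells, flight seedlings and ground seedlings. Not run were the authors' own tables as a source of values (no values per array), a filter on detection calls, the authors' criterion, and the block between ground groups, which could not be fitted. Signal over background limits how many genes can be measured, with 2557 probe sets above it on at least 6 of 12 arrays in cells and 13033 in seedlings.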

Other observations

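The annotation terms and their tests were chosen only after the result was seen. Among 443 annotation terms with 10 to 300 genes, 3 were higher in flight cells by camera: response to high light intensity (38 genes, 27 higher, median 0.74, adjusted p = 1.2e-07), response to heat (125 genes, 77 higher, median 0.38, adjusted p = 2.3e-05) and response to hydrogen peroxide (36 genes, 22 higher, median 0.58, adjusted p = 0.0004). With an estimated correlation no term passed (adjusted p = 1.00, 12 terms at an unadjusted p under 0.05). Of 100 splits of the arrays, 11 gave as many called terms (real 3, highest other 6), so chance cannot be excluded.

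In flight seedlings 8 terms were higher and none lower by camera. With an estimated correlation no term passed (smallest adjusted p = 0.761, 18 terms at an unadjusted p under 0.05). Ribosome biogenesis had 97 of 118 genes higher (median 0.30, adjusted p = 6.8e-05) and chlorophyll biosynthesis 27 of 35 (median 0.65, adjusted p = 8.5e-05). Protein polymerization had a median of 0.59 (adjusted p = 0.00178) and microtubule-based process and movement medians of 0.50 and 0.42 (adjusted p = 0.0188 and 0.0203). Translational elongation (0.43, adjusted p = 0.024), a general protein metabolism term (0.34, adjusted p = 0.00939) and photosynthesis (0.32, adjusted p = 0.0337) completed the set. Of 100 splits, 3 gave as many called terms (real 8, highest other 9), a share under 5% although the highest other split gave more terms than the real one, and brightness of the flight arrays moved with these terms too.

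On ground seedling replicate 1, 30 of 32 heat shock genes were higher than on the other 5 ground arrays, and 19 of the 50 genes with the largest excess were heat shock genes. The small heat shock protein genes HSP17.6A (16.18 against 5.74) and HSP17.6II (15.43 against 5.01) led it. The hypoxia list was higher by a median of 3.11 there, carbon starvation by 1.97 and reactive oxygen by 1.26, while root markers differed by -2.51 and shoot epidermis markers by -2.47. Over the heat shock genes its excess correlated with the flight difference in cells at 0.459, across genes that are not independent, and over all genes at 0.0426.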
